A study of Mus musculus with 6 samples.

How the data were processed

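Total RNA of newborn mouse liver was extracted with an RNeasy kit, labelled as biotinylated cRNA and hybridised to Illumina BeadChips, per the labels' protocols. The 6 arrays were grouped by the genotype in the labels, 3 wild type and 3 Igf2 knockout. The labels do not say whether each array holds 1 pup, or whether pups shared a litter, so p-values measure only the spread between these samples, which may in part be technical. Scan dates, slides and batches were not given in the sources used here.

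The authors deposited 2 tables of probe intensity, on a linear scale. One of them also holds detection p-values, which the deposited columns give per probe and array and which by Illumina's definition are the share of negative control probes as bright as the probe. That table is titled as not normalized, but its values are already background-subtracted and normalized between arrays: about 25.0% to 25.1% of the intensities on each array are below 0, and the sorted intensities of any 2 arrays differ by at most 0.2. Both deposited tables hold the same intensity values. The software and settings behind them are not given in the sources used here. The probe IDs of the table with detection p-values repeat (35746 distinct IDs in 45281 rows), so rows were named through the other table by their 6 intensity values, which no 2 rows share. The IDs differed in 9535 rows, and of 8215 such rows with both IDs named, 8073 had the same gene.

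Of the 45281 probes, 34885 have 1 gene symbol in the platform annotation used here, 18 have several and 10378 have none and stay unnamed. Symbols of 34807 probes were updated through the Entrez gene ID in a RefSeq gene table. No coordinates are given, because the files name no genome build. Illumina probes are short, so a probe of a gene with a close paralog (for example Hamp and Hamp2, or the Acot, Cyp2b and Gsta families) may bind both transcripts.

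The analysis, the gene lists, the rule for named genes and all alternatives except the 3 named last were set before the data were examined. The analysis was set for values not yet normalized and was kept as set. It used limma's neqc (version 3.58.1, in R 4.3.3). This function infers the negative control distribution from the detection p-values (in steps of 1 in 935), subtracts background by normexp, adds an offset of 16, applies quantile normalization and takes log2. Log2 fold changes of dim genes are smaller than the true change because of the offset. Probes with a detection p under 0.05 on at least 3 of 6 arrays were kept (21958 probes, 18429 of them with 1 symbol), and each gene was represented by its kept probe with the highest mean log2 intensity, which left 11346 genes. Other kept probes of the changed genes had the same direction in 1100 of 1249 cases (814 genes). Groups were compared with limma (lmFit and eBayes, two-sided) and Benjamini-Hochberg adjustment over all genes, at an adjusted p of 0.05. Errors of log2 fold changes are limma's moderated standard errors. Where no probe of a gene was above background on any array of 1 group, the fold is a lower bound ("at least"): the mean of the bright group against the mean over the dim group of the higher of the gene's value and the dimmest detected probe on that array.

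The 40 gene lists had 1026 entries, of which 1024 matched a RefSeq symbol or synonym. A list of sex chromosome genes was read per array only, and the other 39 lists were tested with camera (two-sided, preset correlation 0.01), adjusted over the 39 lists. Of 11 lists that passed, 0 passed after adjustment with an estimated correlation (lowest adjusted p = 0.21, and 4 had an unadjusted p under 0.05). With an estimated correlation camera also has only the few degrees of freedom of 6 arrays. A call lost there does not by itself show that genes of the list are correlated. With fry 9 of the 11 lists passed. That test asks whether genes of a list move 1 way on balance and does not compare them with other genes. Genes named in the text come from a rule. It takes Igf2, and the 10 largest rises and 10 largest falls among changed genes whose groups do not overlap and that were detected on all 3 arrays of a group. For lists that passed or hold at least 3 changed genes, it takes up to 3 genes with the smallest p in the direction of the list and up to 2 changed genes the other way. It also takes the gene with the smallest p in other lists, and up to 6 genes of the IGF list and 4 imprinted genes. Not every gene under the rule is printed. The lung markers were listed after the lung transcripts were noticed.

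The comparison of groups was tested on simulated log2 values of independent genes, drawn from the means and spreads of the 11346 genes. There were 3 arrays against 3, with 200 genes changed in each of 10 runs. Background correction, normalization, the filter and the choice of probe were not simulated. The comparison recovered 37.5% of genes changed by 0.5 on the log2 scale, 80.3% of those changed by 1 and 97.6% of those changed by 2, with 4.47% false calls. These rates depend on the share of changed genes, and many more genes (1897) were called in the data. Of 20 simulated lists of 20 genes shifted by 0.3, camera found 20, and it called 0 of 180 unshifted lists, for independent genes. Alternatives changed the background correction, the normalization, the source table, the filter, the choice of probes, the variance model, array weights, a replicate block, a sex covariate, the threshold, the set test and the arrays included. Added after the data were seen were a fit without knockout arrays 1 and 2, a covariate for the mean lung marker signal, and a fit without rows whose probe IDs differ. The first of these leaves 1 knockout array, so the calls that single genes lost in it are not listed gene by gene. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.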

Results

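Liver RNA of newborn mice was hybridised to Illumina expression BeadChips, with 3 wild-type (WT) and 3 Igf2 knockout arrays from a mixed 129 and C57Bl/6 background. Igf2 encodes insulin-like growth factor 2, a hormone of fetal growth that the fetal liver makes in large amounts. The comparison asks how liver gene expression at birth differs in the knockout. Each array carried 45281 probes, of which 46.3% to 49.9% had a detection p under 0.05. The deposited signals had nearly the same distribution on every array, as the deposited normalization between arrays makes them. The number of arrays limits the precision. Across genes, log2 intensities of a pair of arrays correlated at 0.985 to 0.993 within the knockout, 0.987 to 0.991 within WT and 0.967 to 0.977 between genotypes, where genes are not independent replicates.

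Igf2 itself was lower in the knockout. Its only probe named here had a signal of 19218 ± 575 in WT and 10293 ± 1373 in the knockout (SD, n = 3 each), so that 53.6% of the WT signal was left. On the log2 scale Igf2 changed by -0.91 ± 0.11 (SE), with a limma adjusted p of 0.0022. The highest knockout array (13.54) lay below the lowest WT array (14.19). The labels do not say which part of the gene was removed, and where the probe lies relative to it was not analysed here. The remaining signal is therefore not a measure of intact Igf2 transcript.

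Livers of the knockout had higher levels of 16 of 26 measured genes of the urea cycle and amino acid catabolism and of 12 of 20 genes known to respond to glucocorticoids, with 1 gene of each list lower (0 in the first list without any 1 knockout array). Of genes of fatty acid oxidation and ketogenesis, 15 of 24 were lower and 2 higher (0 without WT array 1 or 2 or knockout array 1), and of genes of cholesterol synthesis 9 of 17 were lower and 1 higher. These 4 lists passed a set test with a preset correlation between genes, but not with an estimated one (adjusted p = 0.415, 0.21, 0.415 and 0.483 in the order named). The estimates were 0.19, -0.025, 0.22 and 0.20 in that order, against a preset 0.01, and estimation also leaves the test few degrees of freedom. Tdo2, which opens the degradation of tryptophan, was at least 7.27-fold higher, and Oat, ornithine aminotransferase, was 3.78-fold higher. Acaa1b, a peroxisomal thiolase of fatty acid oxidation, fell by 2.46 on the log2 scale, and Bdh1, which makes the ketone body 3-hydroxybutyrate, fell by 1.55. Of 11346 genes tested, 1897 (16.7%) changed at an adjusted p under 0.05 in limma, 934 of them higher and 963 lower in the knockout. At least 2-fold changes were found for 319 genes, 161 higher and 158 lower. Values of the 3 knockout and 3 WT arrays did not overlap for 4441 genes (39.1%), where chance gives 10%. The count of changed genes was 849 without knockout array 1, 989 without WT array 1, and 1156 with the expression of sex chromosome genes as a covariate. Knockout arrays 1 and 2 also held lung transcripts, and the count was 1144 with their level as a covariate and 228 without both arrays (220 of these among the 1897), where the lone knockout array was assumed to vary like the WT arrays.

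Among changed genes whose groups did not overlap, the largest rises after the lung gene Sftpc were in Hamp2 and Nnmt. Hamp2, a hepcidin gene, was not above background on any WT array and was at least 18.2-fold higher in the knockout (limma adjusted p = 7.63e-05). Nnmt, nicotinamide N-methyltransferase, rose 18.2-fold, from a log2 intensity of 5.03 ± 0.17 to 9.22 ± 0.059 (SD, n = 3 each). Its WT level was near that of the dimmest detected probes on the WT arrays (4.93 to 5.03), so the fold is not exact. Abcg5 and Abcg8, which together form the transporter that exports sterols into bile, rose by 3.29 ± 0.51 and 3.39 ± 0.43 on the log2 scale (SE). Lpin1, a phosphatidate phosphatase, rose by 3.14 ± 0.50, Retreg1, a receptor for autophagy of the endoplasmic reticulum, by 2.93 ± 0.15, and BC018473 by 3.24 ± 0.64. Reg1, a gene of the exocrine pancreas and gut, was at least 15.6-fold higher as a group mean. Its log2 intensity was 9.68, 11.07 and 6.07 on knockout arrays 1, 2 and 3, the first 2 of which also held lung transcripts. Adam32 had the largest fall, at -3.95 ± 0.23 on the log2 scale (SE). Acaa1b (-2.46 ± 0.16), Pcolce2 (-2.43 ± 0.15), Cyp4a12a (-2.35 ± 0.16), Slc17a3 (-2.30 ± 0.10), Rtp3 (-2.17 ± 0.15) and the acyl-CoA thioesterases Acot3 (-2.12 ± 0.16) and Acot4 (-2.11 ± 0.21) followed, with Col27a1 (-2.06 ± 0.14) and Akr1c18 (-2.00 ± 0.22). With 1 array left out, calls were lost for Sftpc without WT array 1, 2 or 3 or knockout array 1 or 2 (adjusted p up to 0.121), Reg1 without WT array 1, 2 or 3 or knockout array 1 or 2 (adjusted p up to 0.124) and BC018473 without knockout array 1 (adjusted p up to 0.0593). Sftpc also lost its call with no filter, the other variance model, the sex covariate and the lung covariate (adjusted p up to 0.131). Reg1 also lost its call with no filter, the other variance model, the replicate block and the sex covariate (adjusted p up to 0.134). BC018473 also lost its call with the other variance model (adjusted p = 0.0701).

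**Figure D1:**
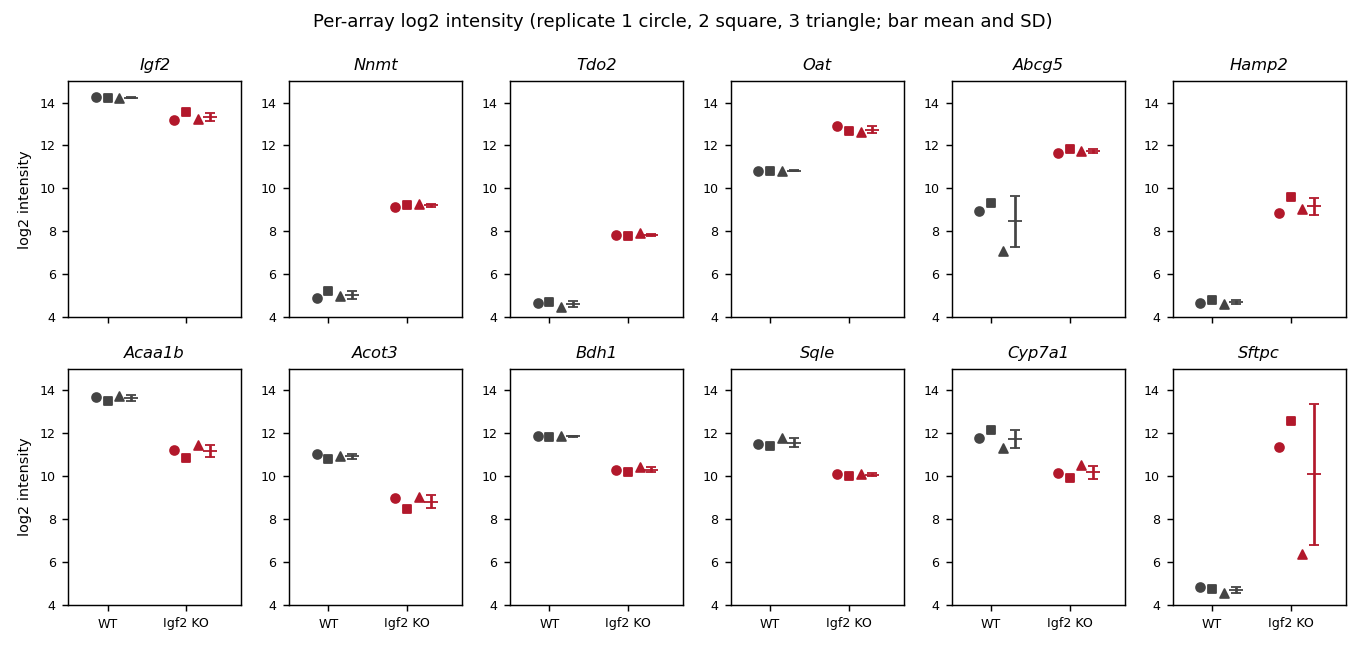
Log2 intensity of 12 genes on each array, WT in grey and the Igf2 knockout in red, where circles, squares and triangles are replicates 1, 2 and 3 and the bars give the mean and SD of 3 arrays. Tdo2 and Nnmt are low in WT and higher on all 3 knockout arrays, while Sftpc is high on knockout arrays 1 and 2 (11.34 and 12.56) and lower on array 3 (6.36).

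Of 26 measured genes of the urea cycle and amino acid catabolism, 16 rose and 1 fell (17 up and 1 down adjusted over the list alone). The median log2 fold change was 0.66, or 0.58 with genes not above background in WT at their lower bound. The list passed limma's camera test (adjusted p = 2.59e-08), but not after the correlation between genes was estimated (adjusted p = 0.415 with an estimated correlation). Besides Tdo2, Oat rose by 1.92 ± 0.10 and Slc25a15, the mitochondrial ornithine carrier, by 1.46 ± 0.085 on the log2 scale (SE). Slc25a13, the aspartate and glutamate carrier citrin, fell (-0.51 ± 0.11), a call that was lost without knockout array 1, 2 or 3 (adjusted p up to 0.0654). Slc25a13 also lost its call with the replicate block, the sex covariate and the lung covariate (adjusted p up to 0.0835). Among 20 genes of the glucocorticoid response, 12 rose and 1 fell (13 up and 1 down adjusted over the list alone). Their median was 0.88, or 0.64 at the bounds. Camera gave an adjusted p of 6.64e-06, and adjusted p = 0.21 with an estimated correlation. Sgk1, a kinase induced by glucocorticoids, rose by 1.60 ± 0.16 and the clock gene Per1 by 1.51 ± 0.16, and Tdo2 belongs to this list too. Nr3c1, which encodes the glucocorticoid receptor, fell (-0.72 ± 0.12). The amino acid list had 0 genes lower without knockout array 1, 2 or 3 or with the sex covariate or the lung covariate or the replicate block and 2 lower without WT array 3.

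Among 24 genes of fatty acid oxidation and ketogenesis, 2 rose and 15 fell (2 up and 17 down adjusted over the list alone). The median was -0.49, and camera gave an adjusted p of 3.22e-08 (adjusted p = 0.415 with an estimated correlation). Besides Bdh1 (-1.55 ± 0.089; SE), the mitochondrial thioesterase Acot2 (-1.88 ± 0.13) and the enoyl-CoA isomerase Eci1 (-1.13 ± 0.083) fell. Cidec, a lipid droplet protein (1.10 ± 0.23), and Pdk4, a kinase that inhibits pyruvate dehydrogenase (0.96 ± 0.22), rose. Of 17 genes of cholesterol synthesis, 1 rose and 9 fell (1 up and 9 down adjusted over the list alone). Here the median was -0.41, with a camera adjusted p of 0.00012 (adjusted p = 0.483 with an estimated correlation). Sqle, squalene epoxidase (-1.48 ± 0.12), Sc5d (-1.28 ± 0.12) and Msmo1 (-1.13 ± 0.12) fell, and Ebp rose (0.55 ± 0.089). Among 21 genes of lipoproteins and lipid transport, 2 rose and 5 fell (2 up and 6 down adjusted over the list alone). This list had a median of -0.13 and a camera adjusted p of 0.0341 (adjusted p = 0.415 with an estimated correlation). Mttp, which loads lipid onto apolipoprotein B (-0.88 ± 0.096), Slc27a2 (-0.67 ± 0.082) and Apob (-0.42 ± 0.082) fell, while Apoc3 (0.92 ± 0.16) and Apoa5 (0.87 ± 0.19) rose. The lipoprotein list lost its call without knockout array 3 (adjusted p up to 0.0538) and with probe means (0.059) and array weights (0.0546), over a range of 0.00259 to 0.415 in all alternatives. Single calls were lost for Cidec without WT array 1 or 2 or knockout array 1 (adjusted p up to 0.0691), Pdk4 without WT array 1 or 2 or knockout array 1 or 3 (adjusted p up to 0.0798) and Apoa5 without WT array 1 or knockout array 1 or 3 (adjusted p up to 0.0804). Pdk4 also lost its call with no filter (adjusted p = 0.0523). Apoa5 also lost its call with the replicate block (adjusted p = 0.0577). The fatty acid oxidation list had 0 genes higher without WT array 1 or 2 or knockout array 1 and 1 higher without knockout array 3. The lipoprotein list had 1 gene higher without WT array 1 or knockout array 1 or 3 or with the replicate block and 3 lower without WT array 1 or knockout array 1.

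Of 12 growth hormone and sex-biased liver genes, 2 rose and 6 fell (3 up and 6 down adjusted over the list alone). The median was -0.69 and the camera adjusted p 0.0289 (adjusted p = 0.415 with an estimated correlation). The list pools male-biased and female-biased genes, so its direction does not measure a shift toward either sex. Cyp4a12a (-2.35 ± 0.16; SE), Acot3 (-2.12 ± 0.16) and Cyp2b13 (-1.51 ± 0.13) fell, and Bcl6 (0.61 ± 0.11) and Cyp7b1 (0.64 ± 0.12) rose. Xist, which is transcribed from an inactive X chromosome, was high on WT array 1 and knockout arrays 1 and 2. With sex chromosome genes as a covariate this list had an adjusted p of 0.02. Among 30 genes of coagulation and complement, 1 rose and 9 fell (2 up and 10 down adjusted over the list alone). Their median was -0.13, with a camera adjusted p of 0.0449 (adjusted p = 0.595 with an estimated correlation). C8a (-0.96 ± 0.086), Mbl1 (-0.98 ± 0.11) and Klkb1 (-0.88 ± 0.14) fell, and C6 rose (0.54 ± 0.14). The call of the first list was lost without WT array 1 or 2 (adjusted p up to 0.0576) and with every probe tested (0.0599), within 0.00241 to 0.415 over all alternatives. That of the second list was lost without WT array 1 or 2 or knockout array 1 or 3 (adjusted p up to 0.101) and with no background correction (0.0529) and the strict filter (0.057), within 6.44e-05 to 0.595 over all alternatives, and its median was -0.082 without knockout array 1. C6 lost its call without WT array 2 or 3 or knockout array 1, 2 or 3 (adjusted p up to 0.0915). C6 also lost its call with no filter, probe means, array weights, the replicate block, the sex covariate, the lung covariate and probes of equal ID (adjusted p up to 0.439). The coagulation list had 0 genes higher without WT array 2 or 3 or knockout array 1 or 3 or with the sex covariate or the replicate block, 3 lower without WT array 1 or knockout array 1 or 3, 4 lower without WT array 2 and 5 lower with the replicate block.

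**Figure D2:**
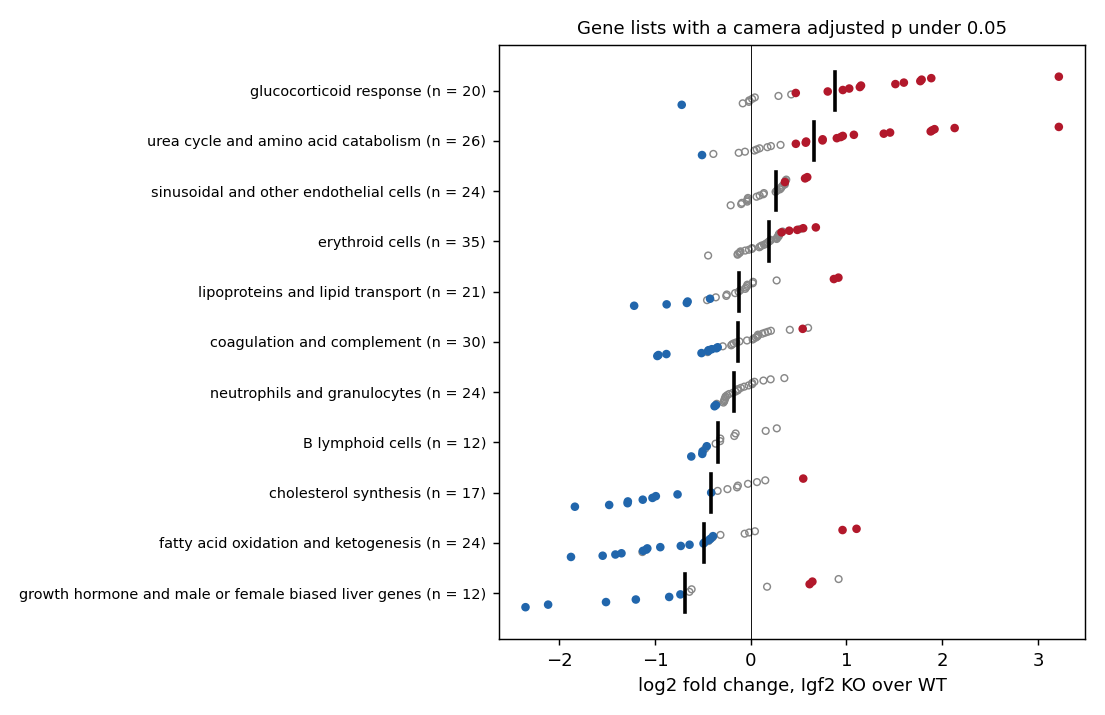
Log2 fold change (Igf2 knockout over WT) of each measured member of the 11 gene lists with a camera adjusted p under 0.05, where filled points passed an adjusted p of 0.05 on their own (red higher, blue lower), open points did not, black bars are medians and n is the number of members measured. The medians run from -0.69 in the growth hormone and sex-biased list to 0.88 in the glucocorticoid list.

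Lists of other liver functions also held changed genes, often in both directions, but did not pass camera in the analysis as set. Camera tests for a shift in a common direction, so rises and falls within a list can cancel in it. In gluconeogenesis, 5 of 12 rose and 1 fell (6 up and 2 down adjusted over the list alone), with a camera adjusted p of 0.0855. The median was 0.46, or 0.28 at the bounds. Gpt, alanine aminotransferase (1.42 ± 0.13; SE), and Pck1, phosphoenolpyruvate carboxykinase (1.14 ± 0.15), rose, and Pcx, pyruvate carboxylase, fell (-0.73 ± 0.095). Tat, tyrosine aminotransferase, was not above background on any WT array and was at least 1.26-fold higher. Tat lost its call with no background correction (adjusted p = 0.1). The gluconeogenesis list passed camera, upward, without WT array 2 (adjusted p = 0.0117), with the sex covariate (0.0483) and in 3 other settings of the probes used, and it passed with fry (0.0417), within 0.0117 to 0.62 over all alternatives. In glycogen metabolism, 2 of 15 rose and 5 fell (3 up and 5 down adjusted over the list alone), with a camera adjusted p of 0.233. Ppp1r3g, a subunit that targets a phosphatase to glycogen, rose (2.78 ± 0.24), whereas the related Ppp1r3c (-1.36 ± 0.22), Stbd1 (-0.86 ± 0.092) and the liver glycogen synthase gene Gys2 (-0.61 ± 0.087) fell. In glycolysis, 2 of 14 rose and 1 fell (5 up and 1 down adjusted over the list alone), with a camera adjusted p of 0.352. Pfkp (0.75 ± 0.15) and Slc2a1, the glucose transporter GLUT1 (0.50 ± 0.11), rose, and Slc2a2, the liver glucose transporter GLUT2, fell (-0.72 ± 0.092). With 1 array left out, calls were lost for Pfkp without WT array 1 (adjusted p up to 0.0624) and Slc2a1 without WT array 1 or 2 or knockout array 1 or 3 (adjusted p up to 0.0809). Slc2a1 also lost its call with the sex covariate (adjusted p = 0.053). The glycogen list had 1 gene higher without WT array 1 or 3 or knockout array 1, 2 or 3 or with the sex covariate or the lung covariate and 3 lower without WT array 1 or 2 or knockout array 1 or with the sex covariate. The glycolysis list had 0 genes higher without WT array 1, 1 higher without WT array 2 or knockout array 1 or with the sex covariate and 2 lower with the sex covariate.

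In bile acid synthesis and transport, 5 of 18 rose and 8 fell (7 up and 9 down adjusted over the list alone), with a camera adjusted p of 0.448. Abcg5 and Abcg8 were among those that rose. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 1.55 on the log2 scale and the bile salt export pump Abcb11 by 1.56, and Akr1d1 was not above background on any knockout array and was at least 1.49-fold lower. The median (-0.20) and the test were downward and the mean (0.17) upward. In fatty acid synthesis, 6 of 20 rose and 5 fell (7 up and 6 down adjusted over the list alone), with a camera adjusted p of 0.927. Scd1, a desaturase, rose (1.85 ± 0.27; SE). Mlxipl, which encodes the carbohydrate-responsive factor ChREBP (-1.51 ± 0.10), Dgat2 (-0.70 ± 0.082) and Agpat2 (-0.91 ± 0.11) fell. Here the median (0.028) and mean (0.13) were upward and the test downward. In xenobiotic metabolism, 7 of 23 rose and 2 fell (8 up and 3 down adjusted over the list alone), with a camera adjusted p of 0.141. Cyp3a13 (1.52 ± 0.12) and Gsta1 (1.32 ± 0.14) rose, and Fmo1 (-1.33 ± 0.12) and Cyp2b9 (-1.20 ± 0.15) fell. Among acute phase genes, 4 of 21 rose and 4 fell (4 up and 4 down adjusted over the list alone), with a camera adjusted p of 0.927. Hamp (2.02 ± 0.25) and Serpina3n (0.68 ± 0.11) rose with Hamp2, and Saa3 (-0.92 ± 0.12) and Saa4 (-1.10 ± 0.15) fell. Of postnatal hepatocyte genes, 6 of 25 rose and 5 fell (8 up and 6 down adjusted over the list alone), with a camera adjusted p of 0.778. For genes of fetal liver, 0 of 13 rose and 0 fell (0 up and 0 down adjusted over the list alone), with a camera adjusted p of 0.187, and 3 of them had an unadjusted p under 0.05. Afp, alpha-fetoprotein, had -0.32 ± 0.099 (adjusted p = 0.0611). The bile acid list had 4 genes lower without WT array 1 or knockout array 1 or 2 or with the sex covariate or the lung covariate and 5 lower without WT array 2. The fatty acid synthesis list had 3 genes lower without WT array 1. The xenobiotic list had 3 genes higher without knockout array 1, 4 higher without WT array 1 and 4 lower without WT array 3. The acute phase list had 2 genes lower without WT array 1 or knockout array 1 or 3 or with the lung covariate or the replicate block. The fetal liver list had 1 gene higher without WT array 3 and 1 lower without WT array 3 or knockout array 2 or with the lung covariate.

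Among p53 targets and cell cycle inhibitors, 3 of 20 rose and 1 fell (5 up and 1 down adjusted over the list alone), with a camera adjusted p of 0.301. Cdkn1a, which encodes the inhibitor p21 (1.89 ± 0.24; SE), Trp53inp1 (1.13 ± 0.15) and Gadd45g (0.90 ± 0.098) rose, and the death receptor gene Fas fell (-1.20 ± 0.11). Of cell cycle genes, 1 of 38 rose and 1 fell (0 up and 0 down adjusted over the list alone), with a camera adjusted p of 0.778. In the hypoxia response, 6 of 19 rose and 0 fell (6 up and 2 down adjusted over the list alone), with a camera adjusted p of 0.17. Ddit4, an inhibitor of mTORC1 signalling (1.78 ± 0.23), had the smallest p there. For the ATF4 and unfolded protein response, 2 of 26 rose and 3 fell (2 up and 6 down adjusted over the list alone), with a camera adjusted p of 0.352. The chaperone genes Pdia4 (-0.78 ± 0.11) and Calr (-0.71 ± 0.14) fell, and Asns, asparagine synthetase, rose (0.57 ± 0.11). Calls were lost for Calr without knockout array 1 (adjusted p up to 0.0598) and Asns without knockout array 1 (adjusted p up to 0.0612). Calr also lost its call with the lung covariate (adjusted p = 0.0595). Asns also lost its call with the sex covariate and the lung covariate (adjusted p up to 0.0607). The ATF4 list had 0 genes higher without knockout array 1 or with the sex covariate or the lung covariate, 1 higher without WT array 1, 2 or 3 or knockout array 3 or with the replicate block, 1 lower without knockout array 1 or with the lung covariate and 5 lower without WT array 2. Among interferon response genes, 0 of 22 rose and 4 fell (0 up and 8 down adjusted over the list alone), with a camera adjusted p of 0.141, with Igtp at -0.95 ± 0.16. Their median was -0.0026, and 0.16 without WT array 1. The interferon list had 3 genes higher without WT array 1, 1 lower without knockout array 1 and 2 lower without WT array 1 or knockout array 3. It passed camera, downward, without WT array 2 (adjusted p = 0.0154), with the sex covariate (0.00991), the lung covariate (0.0292) and array weights (0.0121), within 0.00991 to 0.901 over all alternatives. Of clock genes, 2 of 12 rose and 0 fell (2 up and 0 down adjusted over the list alone), with a camera adjusted p of 0.439, Per1 with the smallest p. Among ribosomal protein genes, 0 of 28 rose and 0 fell (0 up and 0 down adjusted over the list alone), with a camera adjusted p of 0.927, and 2 had an unadjusted p under 0.05 in limma. Their median (0.0088) and mean (0.0098) were upward and the test downward. Of genes of oxidative phosphorylation, 2 of 34 rose and 0 fell (1 up and 0 down adjusted over the list alone), with a camera adjusted p of 0.51. The cell cycle list had 0 genes higher without WT array 2 or knockout array 1, 2 or 3 or with the sex covariate or the lung covariate or the replicate block and 0 lower without WT array 1, 2 or 3 or knockout array 1 or 3 or with the sex covariate or the replicate block. The hypoxia list had 3 genes higher with the sex covariate and 1 lower without WT array 2 or 3 or with the replicate block. The clock gene list had 1 gene higher without WT array 1 or 3 or knockout array 1 or 3 or with the replicate block. The oxidative phosphorylation list had 0 genes higher without WT array 1 or knockout array 1 or with the lung covariate, 1 higher without WT array 2 or knockout array 2 or 3 or with the sex covariate or the replicate block and 1 lower without knockout array 1.

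Within the IGF and insulin system, 1 of 23 rose and 3 fell (2 up and 4 down adjusted over the list alone), with a camera adjusted p of 0.51. Igfals, the acid-labile subunit that holds IGFs in serum complexes (-1.06 ± 0.14; SE), Ghr, the growth hormone receptor (-0.75 ± 0.14), and Igf2r, the receptor that clears IGF2 (-0.70 ± 0.18), fell. The binding protein gene Igfbp5 rose (0.64 ± 0.17). Foxo3 (-0.32 ± 0.092, adjusted p = 0.0509) and the receptor gene Igf1r (0.35 ± 0.11, adjusted p = 0.0608) did not pass. Of imprinted genes, 1 of 28 rose and 2 fell (1 up and 2 down adjusted over the list alone), with a camera adjusted p of 0.293. Phlda2 fell (-1.43 ± 0.24) and Peg3 rose (0.80 ± 0.14), and Gnas did not pass (-0.37 ± 0.11, adjusted p = 0.0577), although it did without WT array 3 (0.0466) or knockout array 2 (0.0466). With 1 array left out, calls were lost for Igf2r without WT array 1 or 3 or knockout array 1, 2 or 3 (adjusted p up to 0.115) and Igfbp5 without WT array 1 or 2 or knockout array 1 or 2 (adjusted p up to 0.131). Igf2r also lost its call with no background correction, no filter, the sex covariate and the lung covariate (adjusted p up to 0.0998). Igfbp5 also lost its call with no background correction, no filter, the replicate block, the sex covariate and the lung covariate (adjusted p up to 0.157). The IGF and insulin list had 0 genes higher without WT array 2 or knockout array 1 or 2 or with the sex covariate or the lung covariate or the replicate block and 2 higher without knockout array 3. The imprinted gene list had 1 gene lower without WT array 1 or knockout array 1 or with the sex covariate and 4 lower without WT array 3.

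Newborn liver still makes blood cells. Of 35 erythroid genes, 5 rose and 0 fell (4 up and 0 down adjusted over the list alone). The median was 0.19 and the camera adjusted p 0.0114 (adjusted p = 0.578 with an estimated correlation). The erythroid call was lost with array weights (0.0546), within 0.000244 to 0.578 over all alternatives. The erythroid list had 1 gene higher without WT array 1 or knockout array 1 or 3, 2 higher without WT array 2 or knockout array 2 or with the sex covariate or the lung covariate or the replicate block and 1 lower without WT array 3. Gfi1b, a transcription factor of red cell and platelet precursors, had the smallest p and rose (0.55 ± 0.082; SE). Among 12 B lymphoid genes, 0 rose and 4 fell (0 up and 5 down adjusted over the list alone). Their median was -0.34, with a camera adjusted p of 0.0165 (adjusted p = 0.595 with an estimated correlation). The surrogate light chain genes Vpreb1 (-0.51 ± 0.087) and Igll1 (-0.46 ± 0.12) fell. Of 24 neutrophil genes, 0 rose and 2 fell (0 up and 0 down adjusted over the list alone). Here the median was -0.17 and the camera adjusted p 0.0223 (adjusted p = 0.595 with an estimated correlation). Ctsg (-0.36 ± 0.090) and Ms4a3 (-0.38 ± 0.099) were the genes that fell. Without knockout arrays 1 and 2, which held lung transcripts, the B lymphoid list had an adjusted p of 0.07 and the neutrophil list one of 0.07. The B lymphoid call was also lost without WT array 2 (adjusted p up to 0.0536) and with fry (0.0876), within 0.000947 to 0.595 over all alternatives. The B lymphoid list had 1 gene lower without WT array 1 or 2 or knockout array 1 or with the sex covariate and 2 lower without knockout array 3 or with the lung covariate or the replicate block. The neutrophil list had 0 genes lower without any 1 of the 6 arrays or with the sex covariate or the lung covariate or the replicate block. The neutrophil call was lost too without knockout array 2 (adjusted p up to 0.058) and with the lung covariate (adjusted p = 0.0786), within 0.00314 to 0.595 over all alternatives. Single calls were lost for Igll1 without WT array 1, 2 or 3 or knockout array 1 or 3 (adjusted p up to 0.113), Ctsg without any 1 of the 6 arrays (adjusted p up to 0.0973) and Ms4a3 without any 1 of the 6 arrays (adjusted p up to 0.105). Igll1 also lost its call with no filter, the replicate block, the sex covariate and the lung covariate (adjusted p up to 0.0995). Ctsg also lost its call with the replicate block, the sex covariate and the lung covariate (adjusted p up to 0.115). Ms4a3 also lost its call with probe means, array weights, the replicate block, the sex covariate and the lung covariate (adjusted p up to 0.139).

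Lists of other blood cells did not pass. Of macrophage and Kupffer cell genes, 3 of 24 rose and 1 fell (3 up and 3 down adjusted over the list alone), with a camera adjusted p of 0.449. Cd14 had the smallest p and rose (0.99 ± 0.16; SE), by 0.85 without knockout array 2 and by 1.18 without knockout array 3. Among megakaryocyte genes, 1 of 16 rose and 0 fell (1 up and 0 down adjusted over the list alone), with a camera adjusted p of 0.91, where the median (-0.012) and the test were downward and the mean (0.014) upward. Of stem and progenitor genes, 0 of 10 rose and 1 fell (0 up and 1 down adjusted over the list alone), with a camera adjusted p of 0.786, where the median (0.0024) was upward and the mean (-0.0060) and the test downward. For mast cells and basophils, 0 of 10 rose and 0 fell (0 up and 0 down adjusted over the list alone), with a camera adjusted p of 0.485. For T and NK cells, 0 of 7 rose and 0 fell (0 up and 0 down adjusted over the list alone), with a camera adjusted p of 0.927. In limma, 1 gene of the mast cell list and 2 of the T and NK cell list had an unadjusted p under 0.05. The macrophage list had 1 gene higher without WT array 1 or 3 or knockout array 1, 2 or 3 or with the sex covariate or the lung covariate or the replicate block, 0 lower without WT array 1 or knockout array 1, 2 or 3 or with the sex covariate or the replicate block and 3 lower without WT array 3. The megakaryocyte list had 0 genes higher without WT array 1 or knockout array 1 and 2 higher without WT array 2. The stem cell list had 1 gene higher without knockout array 3 and 0 lower with the lung covariate. The mast cell list had 1 gene higher without knockout array 3 and 2 lower without WT array 3. The T and NK cell list had 1 gene higher with the sex covariate.

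Transcripts known from lung were present on knockout arrays 1 and 2. Of 28 lung marker genes, listed after this was noticed, 24 were measured, and 14 of these were above background on all 3 WT arrays. Their median log2 difference from the WT mean was 2.06 on knockout array 1, 3.44 on array 2 and 0.016 on array 3. Above every WT array lay 20, 23 and 9 of the 24 markers on knockout arrays 1, 2 and 3. The signal of Sftpc, surfactant protein C, was 2574, 6006 and 66.4 on knockout arrays 1, 2 and 3 and at most 10.7 in WT. That of the airway gene Scgb1a1 was 2287, 7900 and 42.9, and at most 8.1 in WT. Of 24 endothelial genes, some of which lung also expresses, 3 rose and 0 fell (3 up and 0 down adjusted over the list alone). The median was 0.27 and the camera adjusted p 0.0415 (adjusted p = 0.595 with an estimated correlation). Robo4 (0.59 ± 0.091; SE) and Lyve1 (0.57 ± 0.095) rose. The endothelial call was lost without arrays 1 and 2 (adjusted p = 0.229), without WT array 3 or knockout array 2 (adjusted p up to 0.239) and with cyclic loess (0.072), array weights (0.12), the sex covariate (0.163), the lung covariate (0.163) and fry (0.0612), within 0.00399 to 0.595 over all alternatives. Its median was 0.14 without knockout array 2. Of stellate cell and fibroblast genes, 2 of 35 rose and 1 fell (0 up and 0 down adjusted over the list alone), with a camera adjusted p of 0.141. Without knockout array 3 this list passed, with 9 genes higher, 1 lower and an adjusted p of 0.00143 (0.00143 to 0.901 over all alternatives). The stellate cell list had 0 genes higher without WT array 1 or knockout array 1 or with the sex covariate or the lung covariate, 1 higher without WT array 2 or 3 or knockout array 2 or with the replicate block, 9 higher without knockout array 3 and 0 lower without WT array 1, 2 or 3 or knockout array 1 or 2 or with the sex covariate or the replicate block. Among cholangiocyte genes, 1 of 13 rose and 2 fell (2 up and 4 down adjusted over the list alone), with a camera adjusted p of 0.556. The cholangiocyte list had 0 genes higher without WT array 1, 2 or 3 or knockout array 1 or 2 or with the sex covariate or the replicate block, 5 higher without knockout array 3 and 1 lower without WT array 1, 2 or 3 or knockout array 1 or 3 or with the sex covariate or the replicate block. For this list the median (-0.10) and the test were downward and the mean (0.27) upward. In the mesothelium list, 1 of 11 rose and 0 fell (4 up and 1 down adjusted over the list alone), with a camera adjusted p of 0.448. It too passed without knockout array 3 (adjusted p = 0.0442, 0.0442 to 0.978 over all alternatives). Krt19, an epithelial keratin of both lists, rose (1.46 ± 0.37), a call that was lost without WT array 1, 2 or 3 or knockout array 1 or 2 (adjusted p up to 0.111). Krt19 also lost its call with no background correction, no filter, the other variance model, the replicate block and the sex covariate (adjusted p up to 0.102). Its log2 fold change was 1.06 without knockout array 2 and 1.89 without knockout array 3. For neighbouring tissues (pancreas, gut, muscle and fat), 3 of 9 rose and 0 fell (6 up and 0 down adjusted over the list alone), with a camera adjusted p of 0.0892. This list passed, upward, without knockout array 3 (adjusted p = 0.0249), without knockout arrays 1 and 2 (0.00552) and with the lung covariate (0.0278), within 0.00259 to 0.483 over all alternatives. The neighbouring tissue list had 1 gene higher without WT array 1, 2 or 3 or knockout array 1 or with the replicate block. The mesothelium list had 0 genes higher without WT array 1, 2 or 3 or knockout array 1 or 2 or with the sex covariate or the replicate block, 3 higher without knockout array 3 and 1 lower without knockout array 2 or with the lung covariate.

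**Figure D3:**
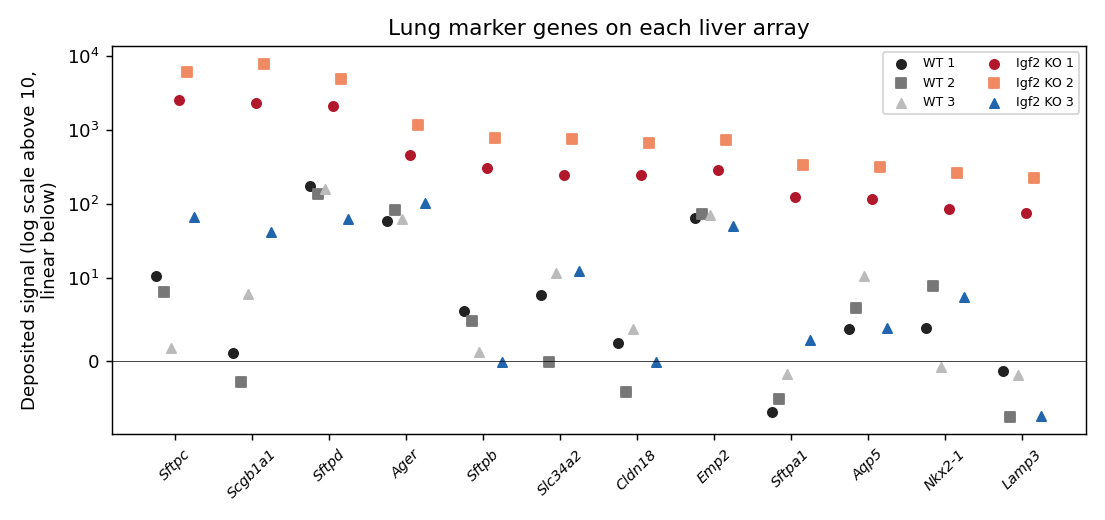
Deposited signal of 12 lung marker genes on each array (log scale above 10, linear below), with WT in grey, knockout arrays 1 and 2 in red and orange and array 3 as blue triangles. For each gene drawn, arrays 1 and 2 lie above all WT arrays, and Sftpc reaches 6006 on array 2.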

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

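Probes without a gene name were outside the comparisons of genes and showed a signal that differed between genotypes. Of 3519 such probes above background, limma called 452 at an adjusted p under 0.05 over these probes, 216 of them higher and 236 lower in the knockout. The genes behind them were not identified here, and no explanation was tested. Groups of 3 arrays were not tested for outlying arrays.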

How the results depend on the processing

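Fits without knockout arrays 1 and 2, with the lung covariate and with probes of equal ID were chosen after seeing the data, the others before. Igf2 stayed lower with an adjusted p under 0.05 in every alternative (log2 fold change -1.03 to -0.84, adjusted p 8.21e-05 to 0.0359). The count of 1897 changed genes stayed within 1.5 times (1709 to 2203) under the other background corrections, normalizations, filters, variance model, source table and probe mean. It was 3088 probes (1801 lower) with every probe tested, 3025 (1591 higher) with array weights, 1156 (571 higher, 585 lower) with the sex covariate, 1144 (583 higher, 561 lower) with the lung covariate, 228 (116 higher, 112 lower) without knockout arrays 1 and 2, 319 (161 higher, 158 lower) at 2-fold or more and 3027 (1566 higher, 1461 lower) at an adjusted p under 0.1. With 1 array left out it ranged from 849 (without knockout array 1) to 1880, with 391 to 953 higher and 458 to 927 lower, and was 989 without WT array 1. Fewer arrays and covariates leave fewer degrees of freedom, and other causes were not tested. With the replicate number as a block 1323 genes changed (627 higher, 696 lower). Arrays of the same number did not deviate together (r = -0.0044, 0.028 and 0.015 across genes), and 0 of 6 correlated best with their own number, so numbers were not taken as pairs. Of 123 named genes that changed, 37 lost their call with at least 1 array left out, 80 without knockout arrays 1 and 2, 24 with the lung covariate and 26 with the sex covariate. Over all alternatives, named genes kept direction and call 2820 times, lost the call 349 times, gained it 59 times and turned 2 times, and gene lists did so 948, 38, 22 and 44 times. Hk1 turned from 0.36 to -0.017 with probe means and Gnas from -0.37 to 0.15 with probes of equal ID, and neither passed in either case. Of the 38 calls lost by lists, 14 were in fits without arrays and 24 in other settings: 11 with an estimated correlation, and those of coagulation with no background correction and the strict filter (0.0529 to 0.057), endothelial with cyclic loess, array weights, the sex covariate, the lung covariate and fry (0.0612 to 0.163), lipoprotein with probe means and array weights (0.0546 to 0.059), growth hormone with every probe tested (0.0599), erythroid with array weights (0.0546), neutrophil with the lung covariate (0.0786) and B lymphoid with fry (0.0876). Calls were gained (adjusted p) by gluconeogenesis with probe means, every probe tested, the sex covariate, probes of equal ID and fry and without WT array 2 (0.0117 to 0.0483), glycogen with fry (0.00316), hypoxia with fry (0.0429), interferon with array weights, the sex covariate and the lung covariate and without WT array 2 (0.00991 to 0.0292), mesothelium without knockout array 3 (0.0442), p53 targets with fry (0.0417), neighbouring tissues with every probe tested, the lung covariate, probes of equal ID and fry and without knockout array 3 or knockout arrays 1 and 2 (0.00259 to 0.0435), stellate cells without knockout array 3 (0.00143) and xenobiotic with every probe tested (0.0282). The 44 list results whose direction turned in camera (or fry) are in lists that passed in neither setting. Their median log2 fold changes follow. For acute phase it was 0.014 as reported, and -0.015 with array weights, -0.0040 with cyclic loess, 0.0091 with the lung covariate, -0.015 with the sex covariate, 0.039 with knockout arrays 1 and 2 left out and -0.0087 to 0.037 with 1 array left out, where the test turned without knockout array 2 or WT array 3. For cell cycle and mitosis it was 0.031 as reported, and -0.0064 with array weights, -0.035 with every probe tested, -0.0069 with probe means, 0.023 with the sex covariate and 0.00034 to 0.092 with 1 array left out, where the test turned without WT array 2. For cholangiocytes it was -0.10 as reported, and -0.18 to -0.011 with 1 array left out, where the test turned without knockout array 3. For fatty acid synthesis it was 0.028 as reported, and 0.042 with no filter, -0.0020 with probes of equal ID, 0.14 with the strict filter, 0.0014 with knockout arrays 1 and 2 left out and 0.0046 to 0.054 with 1 array left out, where the test turned without WT array 1. For mast cells and basophils it was -0.14 as reported, and 0.0088 with the strict filter. For megakaryocytes and platelets it was -0.012 as reported, and 0.023 with array weights, -0.012 with fry, -0.0067 with the lung covariate, 0.0032 with probes of equal ID, 0.041 with the sex covariate, -0.017 with knockout arrays 1 and 2 left out and -0.068 to 0.12 with 1 array left out, where the test turned without knockout array 2 or WT array 2. For mesothelium it was 0.081 as reported, and -0.16 with knockout arrays 1 and 2 left out. For postnatal hepatocyte genes it was 0.030 as reported, and -0.033 to 0.097 with 1 array left out, where the test turned without WT array 3. For ribosomal proteins it was 0.0088 as reported, and 0.0055 with array weights, 0.0073 with every probe tested, 0.0088 with fry, 0.030 with probes of equal ID and -0.022 to 0.0085 with 1 array left out, where the test turned without WT array 2 or 3. For stellate cells, fibroblasts and matrix it was 0.24 as reported, and 0.053 with knockout arrays 1 and 2 left out. For stem and progenitor blood cells it was 0.0024 as reported, and -0.0018 to 0.033 with 1 array left out, where the test turned without knockout array 3. For T and NK cells it was 0.041 as reported, and -0.071 with array weights, 0.015 with an offset of 50, -0.033 with no filter, 0.019 with plain normexp and -0.11 to 0.093 with 1 array left out, where the test turned without knockout array 3 or WT array 2 or 3. The median can keep its sign while the test turns (cause not tested). Only 46.3% to 49.9% of probes were above background on an array, so changes of dim genes are understated or unseen.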

Other observations

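Genes next to Igf2 on its chromosome were compared with all others, in a test chosen after the values were seen. Of the 54 tested genes nearest to it in the order of the RefSeq table, 12 changed (22.2%), against 1884 of 11291 other genes (16.7%). The difference did not pass Fisher's exact test (two-sided, p = 0.273), and 20.5% of windows of 54 neighbouring genes held as many changed genes. By side, 11 of the 30 genes before Igf2 changed and 1 of the 24 after it. These counts were 4 and 1 without knockout array 1, 6 and 1 without WT array 1, 7 and 1 without knockout array 3, 9 and 6 without WT array 3, 7 and 1 with the lung covariate and 2 and 0 without knockout arrays 1 and 2. The sides were told apart only after their values were seen, so their difference is not read as a result. Pnpla2, which encodes adipose triglyceride lipase, rose by 1.49 ± 0.17 (SE) and Sigirr fell (-1.10 ± 0.091), names that were chosen after their values were seen.

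The tested Xist probe had a signal of 1018 on WT array 1, 1984 on knockout array 1 and 1823 on knockout array 2, and at most 17.9 on the other 3. The tested probe of the Y-linked gene Kdm5d was above background on all 6 arrays. Its signal was 97.8, 128.7 and 122.6 on WT arrays 1, 2 and 3 and 51.3, 66.2 and 79 on knockout arrays 1, 2 and 3. The tested probes of Eif2s3y and Uty, also Y-linked, were above background on all 6 arrays too. Eif2s3y had 886.6, 925.3 and 1084.5 on the WT arrays and 684.9, 619.2 and 1054.7 on the knockout arrays. With Y-linked signal on the arrays with high Xist, the sex of those samples was not settled here. On WT arrays 2 and 3 and knockout array 3 the low Xist signal argues against female tissue as a large part of the sample. The knockout arrays with high Xist are those with lung transcripts.

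Tests on lung transcripts, on the genotype labels and on amino acid and fatty acid genes were chosen after the results were seen. Those on other splits of the arrays and on a ceiling of the scale were set before. The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05, where the real split gave 1897 changed genes and the highest of the others 1.

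Knockout arrays 1 and 2 held lung transcripts, and lung tissue or RNA mixed into those samples is a candidate explanation, with Scgb1a1 at 7900 and Sftpc at 6006 on array 2. The excess of all 24 measured markers over WT on array 1 was a median 34.5% of that on array 2, and the quartiles of the ratios (31.1% and 39.1%) lay 7.99 percentage points apart, over a full range of -176% (Rtkn2, with an excess of 7.5 on array 2) to 57.3%, which is in line with 1 mixture at different doses for most but not all markers. A rise of these genes through the genotype stays open: their median difference from WT was 0.016 on the log2 scale on knockout array 3, but a single array does not exclude it. Lung RNA as the whole source of the changed genes is argued against only as far as the lung covariate tracks lung RNA. With it, 519 of 934 higher genes (55.6%) and 519 of 963 lower genes (53.9%) were also called, in the same direction. The covariate is the mean linear signal of the 24 markers and not a pure lung dose. Lyz1, also on the macrophage list, had a signal of 10328, 8881 and 9734 on the WT arrays and 9099 on knockout array 1. The covariate was lower on knockout array 3 (503) than on any WT array. Lung RNA may still raise or lower single genes.

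The knockout kept 53.6% of the WT Igf2 signal. A wrong genotype label on a single array is argued against by the gap of 0.65 on the log2 scale between the lowest WT and the highest knockout array. The gap cannot show whether the knockout samples as a group lack intact Igf2. A ceiling of the scale that hides larger falls stays open, since 0 of 24 genes at least as bright as Igf2 in WT fell by more than Igf2 by over 2 SE (largest fall -0.34), which are too few to decide. A probe outside the removed part, or transcript left in the knockout, was not tested and also stays open.

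Of genes of amino acid catabolism 16 of 26 were higher (1 lower), and of genes of fatty acid oxidation 15 of 24 were lower (2 higher), with a gap of 1.15 between the medians of the lists on the log2 scale, though neither list passed with an estimated correlation (adjusted p = 0.415 each). A lower share of hepatocytes as the whole source of the lower genes is argued against by 62 other liver genes. These came from the coagulation and complement, postnatal and fetal liver lists. Their median was -0.11, and their quartiles (-0.39 and 0.14) both lay above the median of -0.49 for fatty acid oxidation. A lower share as part of the source stays open, since the coagulation list was itself lower (9 of 30 genes, 1 higher). The 62 genes also include some near the top of the scale, such as Ahsg and Kng1, where a fall may be hidden. Some genes of the fetal liver list are also on the imprinted or cell cycle list and need not follow the share of hepatocytes. As the source of this gap, lung RNA in 2 knockout arrays is argued against by a gap of 1.19 with the lung covariate. Unequal sex of the pups is argued against by a gap of 1.18 with the sex covariate. Both hold only as far as the covariates track lung RNA and sex. A shift common to both lists cancels in the gap, so a part of lung RNA in the fall of fatty acid genes was not tested. A response to the loss of Igf2, by way of feeding, hormones or maturity, may underlie the difference and was not tested.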
